A study of Homo sapiens with 6 samples.

How the data were processed

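RNA of ARPE-19 cells cultured for 4 days or 4 months, with 3 samples each, was sequenced on an Illumina HiSeq 2500 in pairs of 50-base reads. Per the labels, total RNA was extracted with a column kit and libraries were made with a stranded mRNA kit, which reads polyadenylated RNA and marks strand. Whether the counting used strand is not given in the sources used here, so genes that overlap an antisense partner cannot be separated. The submitters' processing notes name CASAVA 1, Bowtie 0.12.9 and RSEM 1.2.0 with the builds hg19 and GRCh37. The processed files hold 27939 named entries per sample.

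The deposited expected counts are, per the file headers, RSEM estimates of read pairs per gene and need not be whole (39.4% of them are not). The FPKM and TPM values were scaled by the authors for library size and gene length, per the file headers, and the deposited series table of FPKM is identical to the FPKM in the sample files. The deposited files also hold, per the file headers, other columns: an isoform-weighted transcript length, used only in the closing section, and, left unused here, reads per kilobase, a signal whose definition is not given in the sources used here, an isoform coverage percent and a fraction named tau. The reference at hand is GENCODE v29 on another build (GRCh38) than the files use, so no coordinates are given and it served for gene names and transcript sequences only.

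Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM factors (0.981 to 1.01), a robust quasi-likelihood fit on the 2 durations with no other term, and Benjamini-Hochberg adjustment over the 16764 genes kept (11175 entries were not tested). The threshold was an adjusted p of 0.05, and a 2-fold floor was applied after the test. Standard errors of log2 fold changes are those implied by the F statistic. Totals of 54380967 to 70134367 counts and a biological coefficient of variation of 6.62% gave a median SE of 0.077 for called genes. A gene with no count in a group is given as a bound from a floor of 3 counts over that group, and one with 1 to 3 counts as a ratio with an exact 95% binomial counting interval; both cover counting error only.

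Gene lists (29 lists, 503 entries, all matched to the files, 1 through an older symbol) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01) with Benjamini-Hochberg adjustment over the lists. Members are also counted after adjustment over the list alone. With 73.6% of the tested genes called, that second adjustment could hardly change a call and adds no separate support. The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. That rule takes the 6 largest rises and falls among called genes with at least 5 FPKM in the higher group and separate replicates, a panel of 24 genes, and up to 3 called members per list with at least 1 FPKM in the higher group. The members named because they went against their list (CRIM1, NR2F1, NR2F2, S100A4, OAS1, OAS3, APOC1, ABCA1, VWF, KDR and THY1) were chosen after their values were seen. Some genes that the rule takes are not reported here. Library shares were compared by exact two-sided permutation tests, whose smallest p is 0.1.

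Replicates of a group differed beyond sampling noise (chi-square of 6.74 to 18.3 per gene between pairs), so none was merged. On data simulated from this comparison's means and dispersions with 16605 genes tested, the edgeR step recovered 19 of 50 genes changed 1.2-fold, 38 of 50 at 1.5-fold, 47 of 50 at 2-fold and 50 of 50 at 4-fold, with 18 unchanged genes called. In the set test it called the shifted list and 0 of 28 unchanged ones. The simulated genes varied independently, so this does not show how the set test behaves for lists whose members are correlated. Few simulated genes were changed, whereas 12339 were called in the real data, so the adjusted threshold was stricter in the simulation. The changed genes also left out those with the lowest counts. The recovery of small changes therefore need not hold for the real comparison.

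Alternatives were RLE factors or library size alone, no filter or a mean CPM of at least 1, a replicate block, each sample left out in turn, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a test against a 1.5-fold change, camera with an estimated correlation, fry, and TPM shares. Leaving out structural RNA genes and WDR74, and the shares of structural RNA and histone genes, were added after seeing the data. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and drawn with matplotlib 3.10.9. Sequence scans used the longest annotated 3' UTR of each coding gene. Lengths were tested with limma on log2 length and symbol families with Fisher's exact test. The length test recovered 95 of 100 planted shifts of 0.5 on the log2 scale, with 0 of 9452 unchanged genes called. The family test called the 1 planted family, whose members were all set to rise, and no other. The scan put its planted 7-mer, with an effect of -0.3, at rank 1. Smaller effects were not planted, so recovery of those is not known.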

Results

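ARPE-19 is an established human cell line of the retinal pigment epithelium (RPE), the pigmented cell layer behind the photoreceptors. Its RNA was sequenced after 4 days and after 4 months of culture, with 3 replicate samples at each duration. The total of expected counts was 70134367, 66858317 and 61401207 in the 4-day samples and 56298853, 56046918 and 54380967 in the 4-month samples. Across genes, which are not independent replicates, log2(FPKM + 1) values correlated at 0.995 to 0.998 between samples of a group and at 0.840 to 0.858 between groups. The first principal component held 92.2% of the variance and separated the durations. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

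The comparison asks how gene expression in ARPE-19 cells changed between short and long culture, in a study whose title concerns whether differentiated cells of this line take on a native phenotype. After 4 months the cells expressed RPE65, the isomerase of the visual cycle, which was near the detection limit at 4 days (3 counts over the 3 samples against 4187). The ratio was 1629, with a 95% counting interval of 557 to 7900, and the 3 counts were all in 4 days replicate 3. TYRP1, a pigment synthesis enzyme, rose from 3.77 ± 0.58 to 3750 ± 140 FPKM, and SERPINF1, which encodes the secreted factor PEDF, from 7.76 ± 0.595 to 1479 ± 103 FPKM (mean ± SD, n = 3 per group here and below). In the other direction, MKI67, a marker of dividing cells, fell from 5.45 ± 0.717 to 0.16 ± 0.0557 FPKM. TAGLN, an actin-binding protein of contractile cells, fell from 182 ± 7.6 to 8.52 ± 2.69 FPKM.

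Of the 16764 genes tested, 12339 (73.6%) differed between the durations at an adjusted p below 0.05 in edgeR's quasi-likelihood test, 6208 higher and 6131 lower at 4 months. Because libraries were scaled to each other, higher and lower are relative to the other genes and do not measure RNA per cell. A change of at least 2-fold was fitted for 4474 of them, 2344 higher and 2130 lower, and 407 genes were at least 10-fold higher and 355 at least 10-fold lower. Over all genes tested, called or not, the replicates of the groups did not overlap for 12825, where chance gives 10% of genes. The limma test on log2(FPKM + 1), a scale that shrinks changes of low genes, gave 2373 genes with a 2-fold change.

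**Figure D1:**
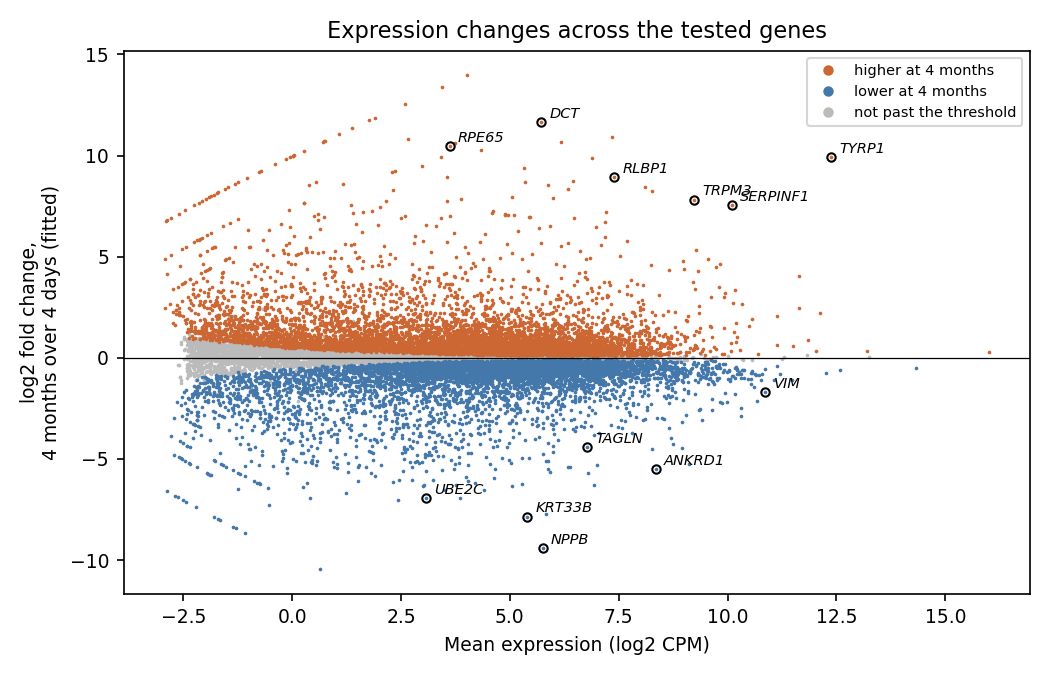
The fitted log2 fold change (4 months over 4 days, y axis) is plotted against the mean expression in log2 CPM (x axis) for 16764 tested genes, each drawn as a point coloured by the edgeR call. DCT, TYRP1, RLBP1, TRPM3, SERPINF1 and RPE65 lie far above 0 and NPPB and KRT33B far below, and the slanted trails of points are genes with no count in 1 group, whose fitted values are not bounds.

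Among genes with at least 5 FPKM in the higher group and separate replicates, the 6 largest fitted rises included those of ERMN, SOHLH2, DCT, DAPL1 and SCGB1D2. ERMN, which encodes a cytoskeletal protein known from oligodendrocytes, had no count at 4 days and 8.84 ± 0.147 FPKM at 4 months, at least 2148-fold higher. SOHLH2, a transcription factor of germ cells, was at least 1456-fold higher (10.4 ± 0.307 FPKM at 4 months), and SCGB1D2 at least 223-fold. Both also had no count at 4 days, so their places among the largest rises come from fitted values. The bound of SCGB1D2 lies below the 979-fold rise of TYRP1, which had counts at both durations. DAPL1 rose from 0.343 ± 0.199 to 664 ± 47.0 FPKM (log2 fold change 10.91, SE 0.13). The 6 largest falls were those of NPPB, KRT33B, SCN9A, UBE2C, HIST1H2BO and ACCN1. NPPB, which encodes a natriuretic peptide, fell from 163 ± 6.82 to 0.24 ± 0.161 FPKM (log2 fold change -9.42, SE 0.14), and SCN9A, a voltage-gated sodium channel, from 13.8 ± 1.08 to 0.0567 ± 0.0115 FPKM. KRT33B was 231-fold, HIST1H2BO 101-fold and ACCN1 91.8-fold lower. The fitted log2 fold change was -10.11 for NPPB without 4 months replicate 3, -7.29 for HIST1H2BO without 4 months replicate 2 and 12.61 for DCT without 4 days replicate 3, which held 4 of its 6 counts at 4 days. KRT33B and HIST1H2BO have closely related copies between which read pairs are divided by estimation, so their values are uncertain.

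**Figure D2:**
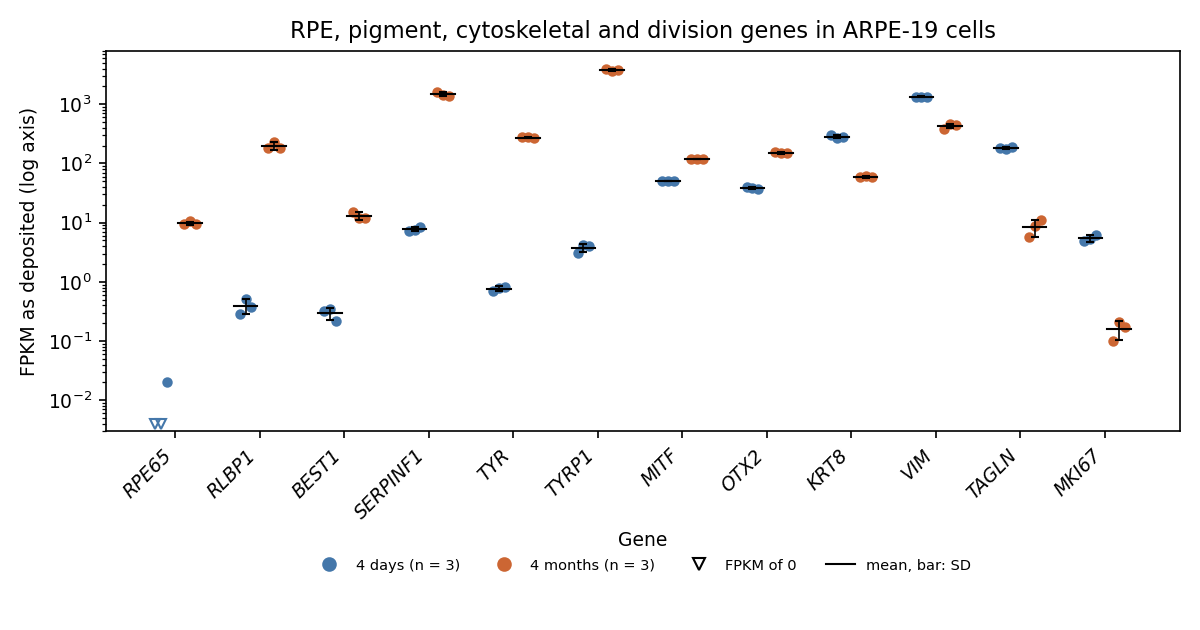
FPKM as deposited (log y axis) of 12 genes (x axis) in each of the 6 samples, with points for replicates at 4 days (blue) and 4 months (orange), lines for group means, bars for the SD, and open triangles for an FPKM of 0. No mean is drawn for RPE65 at 4 days, where the SD exceeded the mean, and the groups do not overlap for any of the 12 genes.

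Visual cycle genes rose together: all 12 measured members of the list were higher at 4 months, and 12 were when adjusted over the list alone. The camera test gave an adjusted p of 4.92e-06 for the list (adjusted p = 0.0977 with an estimated correlation). RLBP1, the retinaldehyde-binding protein, rose from 0.393 ± 0.111 to 198 ± 27.8 FPKM (adjusted p 2.05e-09). RDH5, a retinol dehydrogenase, was 24.8-fold higher, and LRAT, which esterifies retinol, 22.1-fold higher. RDH10, already at 90.3 ± 1.97 FPKM at 4 days, was 1.97-fold higher. TTR, which carries retinol-binding protein, had no count at 4 days and was at least 228-fold higher at 4 months, and RGR, an opsin of the RPE, rose from 0.0167 ± 0.0153 to 16.0 ± 2.74 FPKM.

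Pigment genes rose as well, with 14 of 14 measured members of the melanosome list higher over all genes and 14 adjusted over the list alone (camera adjusted p 1.57e-07; adjusted p = 0.184 with an estimated correlation). TYR, which encodes tyrosinase, rose from 0.767 ± 0.0709 to 273 ± 4.80 FPKM, and DCT, the dopachrome tautomerase, from 0.0167 ± 0.0115 to 47.3 ± 5.85 FPKM (log2 fold change 11.67, and 12.61 without 4 days replicate 3). OCA2, a melanosomal transporter gene, was at least 815-fold higher. In the list of RPE signature and secreted factors, 16 of 18 measured members were higher and 1 lower, the same counts as adjusted over the list alone (camera adjusted p 4.16e-07; adjusted p = 0.0977 with an estimated correlation). BEST1, a chloride channel of the RPE, was 45.3-fold higher, and TRPM1 and TRPM3, ion channel genes, rose by 10.68 and 7.82 on the log2 scale. SFRP5 was at least 130-fold higher, VEGFA 2.83-fold higher, and CRIM1 was the member that fell, from 273 to 141 FPKM.

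Of the RPE transcription factors, 9 of 12 were higher and 2 lower, over all genes and adjusted over the list alone (camera adjusted p 0.0128; adjusted p = 0.184 with an estimated correlation). MITF and OTX2, which control pigment and RPE genes, were already at 50.9 ± 0.332 and 38.3 ± 1.66 FPKM at 4 days and reached 119 ± 1.37 and 150 ± 3.33 FPKM. TFEC, a relative of MITF, was 52.3-fold higher, RAX 9.22-fold and SOX9 4.36-fold. NR2F1 and NR2F2 were the members that fell, with log2 fold changes of -0.20 and -0.63. Of 18 measured ion and metabolite transport genes, 14 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p 0.00162; adjusted p = 0.175 with an estimated correlation). KCNJ13, an apical potassium channel gene of the RPE, had 1 count at 4 days, in replicate 2, and 2186 at 4 months, a ratio of 2551 with a 95% counting interval of 457 to 100793. CA14 and CA2, carbonic anhydrase genes, were 14.3-fold and 14.1-fold higher.

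Of 14 measured genes of outer segment phagocytosis, 4 rose and 10 fell, as they did adjusted over the list alone, and the list did not pass (camera adjusted p 0.139). MERTK, the receptor tyrosine kinase of outer segment uptake, was 16.6-fold higher, whereas its relatives AXL and TYRO3 were 9.90-fold and 7.45-fold lower. Of 16 junction and polarity genes, 8 rose and 5 fell over all genes and adjusted over the list alone (camera adjusted p 0.515). The set test fry put the junction list lower (adjusted p 0.000281, range over its alternatives 0.000281 to 0.741), against a median log2 fold change of 0.41 and a mean of 0.48. CDH1 and CDH3, the cadherins of epithelia, rose but stayed low, from 0.0433 ± 0.0153 to 0.573 ± 0.0551 FPKM and from 0.02 ± 0.0173 to 0.497 ± 0.104 FPKM (log2 fold change of CDH3 4.63, and 5.25 without 4 days replicate 3). CLDN2 rose from 0.0167 ± 0.0115 to 3.51 ± 0.851 FPKM, CLDN1 was 7.36-fold lower, and CLDN4, with no count at 4 months, was at least 161-fold lower. All 5 measured keratins of simple epithelia fell, 5 of 5 adjusted over the list alone too (camera adjusted p 0.00172; adjusted p = 0.184 with an estimated correlation). KRT8 fell from 283 ± 16.4 to 59.2 ± 1.99 FPKM, KRT7 was 8.57-fold lower and KRT80 10.9-fold lower.

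Mesenchymal and contractile genes fell, with 16 of 19 measured members lower and 1 higher over all genes and adjusted over the list alone (camera adjusted p 8.61e-05; adjusted p = 0.184 with an estimated correlation). VIM, an intermediate filament gene, fell from 1339 ± 14.3 to 426 ± 36.7 FPKM, TPM1 was 7.23-fold lower, ACTA2, the smooth muscle actin, 6.55-fold, COL5A2 6.74-fold and COL1A1 3.27-fold. S100A4 was the member that rose, from 4.36 to 7.71 FPKM. All 19 targets of YAP and SRF, regulators that respond to cell spreading and actin, fell, 19 also adjusted over the list alone (camera adjusted p 1.91e-07; adjusted p = 0.184 with an estimated correlation). ANKRD1 fell from 326 ± 6.61 to 7.39 ± 2.12 FPKM, and EDN1 was 32.0-fold lower (51.0-fold without 4 months replicate 3).

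Genes of cell division fell: 22 of 22 mitosis genes, each by at least 2-fold, and 24 of 24 DNA replication genes, 19 of them by at least 2-fold, with the same counts of calls adjusted over each list alone. Their camera adjusted p were 5.13e-10 and 6.44e-09 (adjusted p = 0.184 and 0.206 with an estimated correlation). UBE2C was 123-fold, KIF20A 91.7-fold and BIRC5 77.4-fold lower, and MCM10 was 28.6-fold, CDC45 22.9-fold (41.4-fold without 4 months replicate 3) and CCNE2 22.3-fold lower. Of 14 cell cycle inhibitors and senescence genes, 3 rose and 9 fell, over all genes and adjusted over the list alone (camera adjusted p 0.0364; adjusted p = 0.184 with an estimated correlation, and 0.0504 with a filter at a mean CPM of 1, in a range of 3.27e-06 to 0.184 over its alternatives). CDKN1A, which encodes p21, was 4.27-fold lower, while CDKN1C, which encodes p57, was 5.73-fold higher. Of 11 measured inflammatory and secretory genes, 3 rose and 6 fell, as adjusted over the list alone (camera adjusted p 0.319), among them IL8 at 11.8-fold, IGFBP3 at 11.2-fold and LIF at 4.50-fold lower.

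Complement genes rose, with 14 of 18 measured members higher and 4 lower over all genes and adjusted over the list alone (camera adjusted p 0.00232; adjusted p = 0.175 with an estimated correlation). CLU, which encodes clusterin, rose from 24.2 ± 0.809 to 618 ± 40.7 FPKM, and CFI, complement factor I, from 2.82 ± 0.0586 to 68.2 ± 2.54 FPKM. Of 17 interferon-stimulated genes, 11 rose and 2 fell over all genes and adjusted over the list alone (camera adjusted p 0.0189; adjusted p = 0.184 with an estimated correlation). IFIT1 was 14.2-fold and IFI6 3.09-fold higher, and the members that fell were OAS1 and OAS3.

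Most genes of cholesterol synthesis fell and most of cholesterol efflux rose. Of 19 cholesterol synthesis and uptake genes, 4 rose and 15 fell over all genes and adjusted over the list alone (camera adjusted p 0.0118; adjusted p = 0.206 with an estimated correlation). HMGCS1 was 2.10-fold and MVD 2.64-fold lower, and INSIG1 2.90-fold higher. Of 12 efflux and lipoprotein genes, 10 rose and 2 fell by both counts, adjusted over the list alone included (camera adjusted p 0.00636; adjusted p = 0.205 with an estimated correlation). ABCG1, a sterol exporter, was 55.3-fold higher, CYP27A1 14.7-fold and APOE 13.9-fold, while APOC1 and ABCA1 fell. Of 22 lysosome and autophagy genes, 15 rose and 3 fell over all genes, and 15 rose and 4 fell adjusted over the list alone (camera adjusted p 0.0126; adjusted p = 0.206 with an estimated correlation). CTSK, a secreted cathepsin, rose from 34.4 ± 1.98 to 691 ± 23.4 FPKM, and TFEB was 3.16-fold and CTSL1 2.74-fold higher.

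In energy metabolism, 13 of 19 glycolysis genes fell and 4 rose by both counts, adjusted over the list alone included (camera adjusted p 0.0166; adjusted p = 0.369 with an estimated correlation). PFKFB3 was 3.10-fold, PFKP 2.30-fold and PGK1 2.05-fold lower. Of 23 nuclear genes of the citrate cycle and respiratory chain, 20 rose and the other 3 did not pass, over all genes and adjusted over the list alone (camera adjusted p 3.02e-05; adjusted p = 0.206 with an estimated correlation). PPARGC1A, a coactivator of mitochondrial genes, rose from 1.31 ± 0.0954 to 39.5 ± 1.07 FPKM, IDH2 was 3.06-fold higher and OGDH 2.99-fold higher.

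A further 3 lists did not pass as sets, and their counts adjusted over the list alone equalled those over all genes. Of 24 genes of basement membranes, 12 rose and 9 fell (camera adjusted p 0.925): NID2 was 85.4-fold and ELN, elastin, 24.7-fold higher, and COL4A1 8.49-fold lower. Of 20 oxidative stress genes, 12 rose and 7 fell (camera adjusted p 0.215), with SOD3 10.8-fold and GPX3 4.57-fold higher and TXNRD1, a thioredoxin reductase, 4.62-fold lower. Of 15 genes of the unfolded protein response, 4 rose and 10 fell (camera adjusted p 0.0975), with ATF3 30.3-fold, PPP1R15A 3.54-fold and TRIB3 3.20-fold lower.

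Markers of other retinal cells moved in part, and for each of these lists the counts adjusted over the list alone equalled those over all genes. In the list of photoreceptor and retinal neuron genes, 7 of 20 were measured, of which 5 rose and 1, THY1, fell (camera adjusted p 0.0475, and 0.206 with an estimated correlation). That call was also lost with library size alone (adjusted p 0.0547), with no filter (0.0985) and without 4 days replicate 3 (0.0507), 4 months replicate 1 (0.0539) or 4 months replicate 2 (0.0629), in a range of 3.27e-06 to 0.206 over its alternatives. GNGT1, a transducin subunit, rose from 0.0567 ± 0.0208 to 18.5 ± 1.55 FPKM and ROM1 was 2.52-fold higher, while SAG had 0 counts at both durations. Of 7 Müller glia genes, 4 rose and 3 fell (camera adjusted p 0.466), with GLUL, glutamine synthetase, 9.28-fold higher; RLBP1 and VIM stand in this list too. Of 4 measured melanocyte genes, DCT and MLANA rose (camera adjusted p 0.215), and both stand in the pigment list. Of 6 endothelial and pericyte genes, 2 rose and VWF and KDR fell (camera adjusted p 0.867), with a median log2 fold change of 0.26 and a mean of -0.75. Among them PDGFRB was 1.85-fold and RGS5 1.21-fold higher, and RGS5 did not pass without 4 days replicate 1 (adjusted p 0.0850, range over its alternatives 0.000294 to 0.0850). Of 6 macrophage genes, CSF1R rose 16.7-fold and CD68 was 1.78-fold lower (camera adjusted p 0.466).

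**Figure D3:**
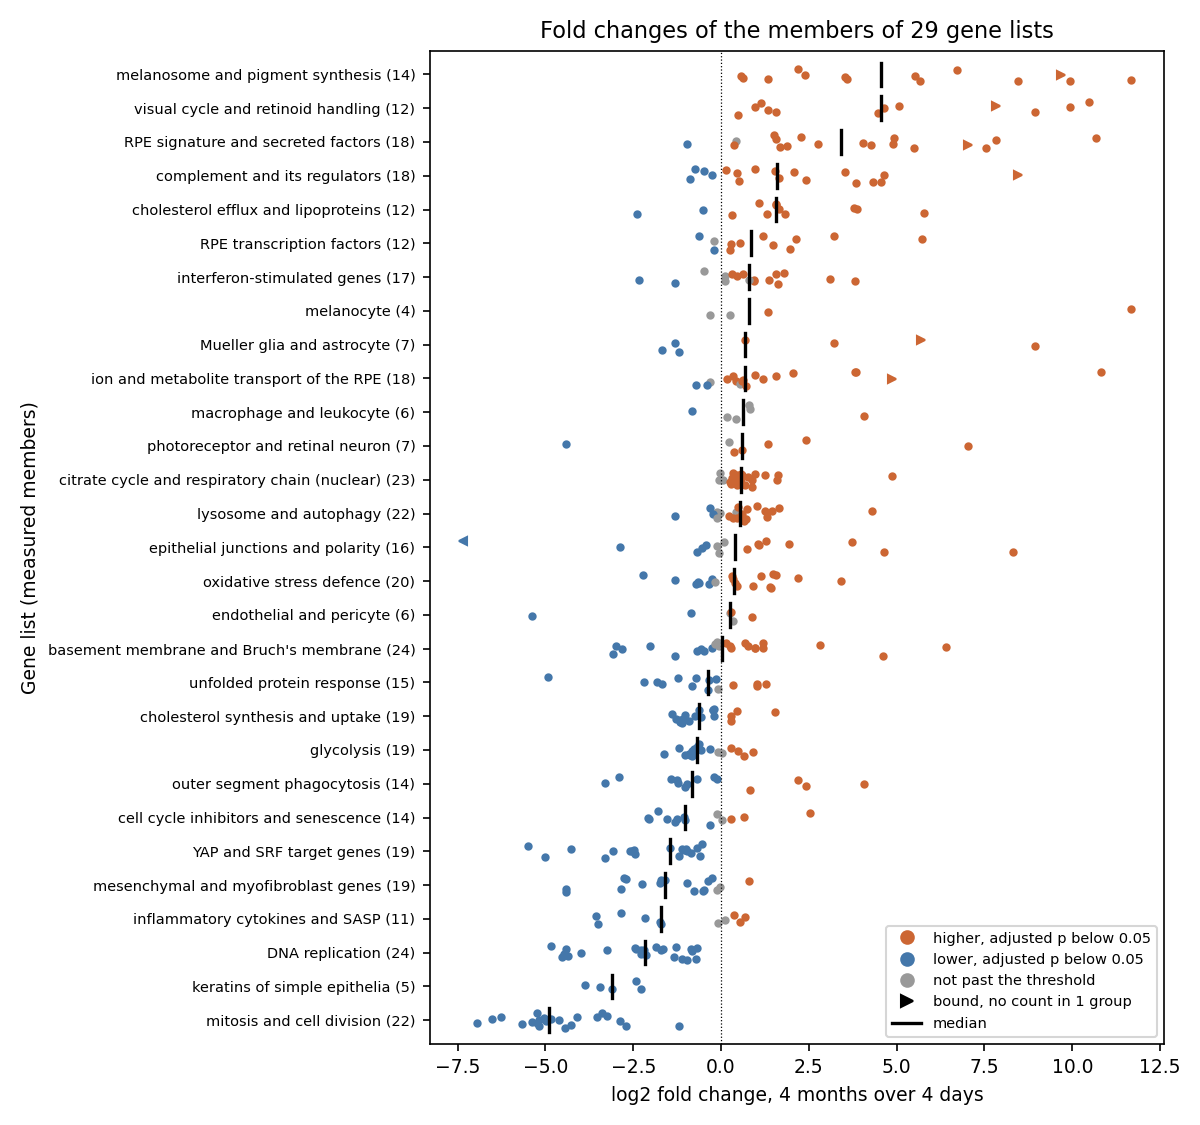
The log2 fold change (4 months over 4 days, x axis) of each measured member of the 29 gene lists (y axis, with the number of measured members), with points coloured by the edgeR call, a black tick at each list median, and triangles at the bound for 7 members with no count in 1 group. The lists run from mitosis and cell division, with a median of -4.91, to melanosome and pigment synthesis, with a median of 4.56.

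The composition of the libraries differed between the durations. Ribosomal protein genes held 7.08 ± 0.240% of the counts at 4 days and 4.31 ± 0.1702% at 4 months (SD, n = 3), and the 10 genes with the highest counts 12.7 ± 0.595% and 15.02 ± 0.377%. Genes with at least 1 FPKM numbered 12333 ± 11.02 at 4 days and 12584 ± 51.4 at 4 months, and histone genes held 0.159 ± 0.00513% and 0.0818 ± 0.00404% of the counts. Each of these gave p = 0.1 in an exact two-sided permutation test, the smallest p that 3 samples against 3 allow. The count of detected genes depends on the measure. By the submitters' own detection calls, which were not tested here, fewer genes were detected at 4 months (15786 to 15900) than at 4 days (16231 to 16353). Structural RNA genes, which include 7SL and 7SK RNA, held 8.63 ± 0.573% at 4 days and 9.75 ± 0.514% at 4 months, and the exact permutation p was 0.2. As shares of summed TPM the differences were in the same directions and larger, at 5.60 percentage points for structural RNAs (1.12 by counts), -4.93 for ribosomal protein genes (-2.77), 4.78 for the 10 highest genes (2.33) and -0.201 for histone genes (-0.0771). A pair of mitochondrially encoded entries held 0.009999 ± 0.000268% and 0.0210 ± 0.00272% of the counts, again with an exact permutation p of 0.1.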

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

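The test of the length column, and its check on other splits, was chosen only after the main results were seen. RSEM writes for each gene a transcript length weighted by the estimated share of each isoform, a column that no comparison above uses, and a change in it means that the estimated isoform mix changed. It was called different between 4 days and 4 months, by at least 0.25 on the log2 scale, for 76 of 9552 genes with several lengths (limma, adjusted p below 0.05), 41 longer and 35 shorter at 4 months; 498 were called at any size. TRPM3, the host gene of miR-204, went from a mean length of 3551 to 1903 bases while its counts rose 226-fold (log2 length change -0.90, SE 0.06, adjusted p 0.00595). Its FPKM rose more than its counts as a result, from 1.497 ± 0.150 to 648 ± 65.5 (SD, n = 3). SYNE2, a giant nuclear envelope protein gene, went from 11541 to 16091 bases, TLN2 from 6164 to 9314, NBEA from 9824 to 6620 and KIF22 from 1674 to 706. These 5 genes were chosen after their values were seen. The real grouping gave 76 such genes and 1 of the 10 splits of the 6 samples gave as many, the real one. The highest other split gave 0, and 10 splits are too few for a share under 0.05. The other splits also mix the durations within their groups, so few calls could come out of them. Short reads do not phase exons, and no explanation of the length changes was tested.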

How the results depend on the processing

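Leaving out structural RNAs and WDR74, and the shares of structural RNAs and histones, were tests chosen after seeing the data; the splits and the other alternatives were fixed before. The count of called genes lay between 11043 and 12732 over the alternatives to that test, and every call these shared with it had the same direction except 4 with limma on FPKM. The test against a 1.5-fold change was an alternative for genes called with at least a 2-fold change alone (5839 against 4474), and shared calls were not counted for it. The median log2 fold change of all genes stayed between 0.01 and 0.07, and the share of calls that were higher between 48.0% and 52.2%. Each alternative scales the libraries to each other, so a median near 0 is largely built in and does not check the scaling. With limma on log2(FPKM + 1), 2373 genes had a 2-fold change (1204 higher, 1169 lower). With the replicate block, 12206 genes were called, 12112 of them shared. The deviations of same-numbered samples correlated at 0.04, -0.03 and 0.04, and those of differently numbered samples at -0.07 to 0.03. No strong pairing by number shows, but a weak one could not be seen this way. Camera called 19 of 29 lists with the preset correlation and 0 with an estimated one (7 at an unadjusted p below 0.05), and fry called 28. With an estimated correlation, camera also refers its statistic to the 4 residual degrees of freedom, so the lost calls do not measure correlation alone. The estimates lay below the preset 0.01 for visual cycle (-0.064) and RPE signature (-0.034). They lay above it for mitosis (0.329) and DNA replication (0.526). The estimated adjusted p was 0.0977 for visual cycle and RPE signature, 0.175 for ion transport and complement, 0.184 for melanosome, RPE transcription factors, keratins, mesenchymal, YAP and SRF, mitosis, cell cycle inhibitors and interferon-stimulated genes, 0.205 for cholesterol efflux, 0.206 for DNA replication, cholesterol synthesis, lysosome, citrate cycle and photoreceptor genes, and 0.369 for glycolysis. By fry, which does not compare a list with other genes, these also passed: phagocytosis (0.00166), inflammatory genes (0.00116), basement membrane (0.0247), oxidative stress (0.000179), unfolded protein response (0.000266), Müller glia (2.27e-06), melanocyte (0.000108) and macrophage (0.0199); junctions passed in the opposite direction, lower (0.000281). With a mean CPM of at least 1, cell cycle inhibitors gave 0.0504. RGS5 was not called without 4 days replicate 1 (adjusted p 0.0850); the other 1741 comparisons of a named gene with an alternative kept direction and call, as did 372 such comparisons of a list. The photoreceptor list gave 0.0547 with library size alone, 0.0985 with no filter, and 0.0335 to 0.0629 with 1 sample left out; it did not pass without 4 days replicate 3 (0.0507), 4 months replicate 1 (0.0539) or 4 months replicate 2 (0.0629). As TPM shares, the differences in percent were 4.78 for the 10 highest genes, 0.0136 for the mitochondrial entries, -4.93 for ribosomal protein genes, 5.60 for structural RNAs and -0.201 for histones, all in the same direction. Leaving out structural RNAs and WDR74 kept 12275 of the calls. The cause of these changes was not tested. Of the 10 splits of the samples, only the real one gave as many calls (12339 genes, 4474 with a 2-fold change, 19 lists, 1 of 10 each). The highest other split gave 0 genes, 0 genes with a 2-fold change and 13 lists, and 10 splits are too few for a share under 0.05. Every other split mixes the durations, so their difference widens the spread within its groups. The 0 genes there were therefore nearly fixed in advance and decide nothing. Camera with the preset correlation still called 7 to 13 of the 29 lists in those other splits. Their groups hold the durations in unequal numbers, so part of the real difference remains, and these list calls give no rate of false calls. In the simulation, where few genes changed, 19 of 50 changes of 1.2-fold were called, a share that need not hold for the real comparison.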

Other observations

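The scan of symbol families and the tests on other cell types, structural RNA and WDR74 were chosen only after the main results were seen; the miRNA site test was fixed before its result was seen, except its repeats without the genes of the fixed lists and among common 7-mers. Among 90 families of symbols with at least 15 tested members, 14 were enriched among genes with a 2-fold change in one direction (Fisher's exact test, adjusted p below 0.05 over 180 tests). The test treats genes as independent, which members of a family need not be, so its p-values may be too small. Solute carriers were enriched among the rises, with 67 of 269 SLC genes at least 2-fold higher and 26 at least 2-fold lower (adjusted p 0.000101 for higher). SLC16A14 rose from 0.113 ± 0.0115 to 41.1 ± 1.94 FPKM, SLC7A8, an amino acid transporter, from 1.12 ± 0.0757 to 69.8 ± 8.69 and SLC2A12, a sugar transporter, from 1.33 ± 0.0929 to 73.6 ± 2.62 (SD, n = 3). Aldehyde dehydrogenases were also enriched among the rises, with 8 of 18 at least 2-fold higher and 0 at least 2-fold lower (adjusted p 0.0295 for higher). ALDH1A3, which makes retinoic acid, went from 255 ± 8.76 to 1094 ± 27.4 FPKM, and CYP26A1, which degrades it, from 0.11 ± 0.0529 to 2.34 ± 0.243. The same held for tetraspanins (8 of 19 at least 2-fold higher and 2 lower, adjusted p 0.0333), cytochromes P450 (9 of 23 and 4, adjusted p 0.0333) and GPR receptors (17 of 46 and 6, adjusted p 0.00311), although most of their members did not reach a 2-fold rise. TSPAN10 rose from 8.54 ± 0.295 to 109.8 ± 15.98 FPKM.

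Histone genes were enriched among the falls, with 34 of 52 at least 2-fold lower and 1 at least 2-fold higher (adjusted p 2.03e-16 for lower), although their near-identical copies and the lack of a poly(A) tail on most of their transcripts make single values uncertain. ADAMTS genes, most of them secreted proteases, were enriched too, with 10 of 18 entries at least 2-fold lower and 2 at least 2-fold higher (adjusted p 0.000801; 1 of the entries is the antisense gene ADAMTS9-AS2). ADAMTS5 went from 17.0 ± 1.73 to 1.43 ± 0.221 FPKM and ADAMTS12 from 18.4 ± 0.987 to 2.52 ± 0.353. Kinesins (15 of 34 at least 2-fold lower and 6 higher, adjusted p 0.000358), RGS genes (8 of 16 and 2, adjusted p 0.0086), genes whose names begin with SH (12 of 32 and 5, adjusted p 0.0086) and CDC genes (11 of 33 and 0, adjusted p 0.0295) were also enriched among the falls. KIF11, KIF20A, CDC6, CDC20 and CDC45 also stand in the mitosis and DNA replication lists above, so those families partly repeat that result. Families that were enriched among the falls but went both ways were IL genes (13 of 37 at least 2-fold lower and 4 higher, adjusted p 0.00896, median log2 fold change 0.08), collagens (10 of 27 and 7, adjusted p 0.0232, median -0.12) and cadherins (7 of 16 and 5, adjusted p 0.0319, median -0.46). COL12A1 went from 100.3 ± 6.81 to 2.84 ± 0.289 FPKM and COL11A1 from 89.8 ± 2.16 to 11.1 ± 1.66. The genes named for a family were chosen after their values were seen. The medians of the 14 families kept their signs with RLE factors and with library size alone. The real grouping called 14 families and the highest other split 0. Of the 10 splits 1, the real one, gave as many, which is too few splits for a share under 0.05. As other splits mix the durations and called 0 genes, they could call no family.

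The joint rise of pigment, visual cycle and RPE genes, with a median log2 fold change of 4.16 over the 3 lists, was set against 3 technical explanations. Melanocytes in the cultures would bring their own genes, but 1 of 7 melanocyte genes (MLANA) was called higher with at least 1 FPKM, and SOX10 had 5 counts and PAX3 and KIT 0 counts at 4 months. Photoreceptors would bring their abundant transcripts, but SAG, GNAT1 and PRPH2, chosen after the main results were seen, together had 3 counts at 4 months beside 2062 for GNGT1. In the list of photoreceptor and retinal neuron genes 13 of 20 members were too low to be tested. Of the 7 measured, 5 rose, ROM1 2.52-fold and PDE6B 1.52-fold among them. The 1 that fell, THY1, also stands in the mesenchymal list. The markers of photoreceptors point both ways, as SAG, GNAT1 and PRPH2 had almost no counts while GNGT1, ROM1 and PDE6B rose. Leaving out the structural RNAs moved the median by 0.000243, but their shares were too close between the durations for this to have come out otherwise, so it decides nothing. The data are in line with the hypothesis of a change of state of the cells with time in culture, which cannot be separated here from selection of a part of the cells or from any difference in handling between the durations.

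Structural RNAs were abundant for libraries made with an mRNA kit: they held at least 8.11% and up to 10.1% of the counts, and the 7SL entry alone 5.31 to 7.48%. How they came into the libraries was not tested. WDR74 held 0.331 to 0.511% of the counts. All 191 bases of the U2 small nuclear RNA gene RNU2-2P lie within 2 of 17 annotated WDR74 transcripts, so its counts may include U2 reads, but the entry named U2 fell (57.3 to 14.9 CPM, log2 fold change -1.97, adjusted p 0.000387) while WDR74 rose by 0.34 on the log2 scale, and the explanation stays open. ZNF277, at 0.323 to 0.388% of the counts, shares no more than 11 consecutive bases with U2.

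TRPM3 and TRPM1 host the microRNAs miR-204 and miR-211, which share a seed and were not measured here, and a hypothesis was that genes with their site fell. In 13665 genes with an annotated 3' UTR (99.3% of the coding genes matched), carriers of the 7-mer AAAGGGA (2684 genes) had an effect on the log2 fold change of -0.13 (SE 0.03), with UTR length, GC content and expression in the model, and medians of -0.05 with and -0.02 without the site. Ordered by the effect over its SE the 7-mer ranked 3 of 16383 from the lowest, and 1 without the genes of the fixed lists; by size alone its percentile was 2.88 among all 7-mers, and its rank 4 of 10054 among those found in at least 1000 genes. The limits set beforehand, 1% for a fit and 5% against, were for all 7-mers, and the orders fall on different sides of the first, so repression by these microRNAs may contribute but stays open, and other 7-mers (ranks 1 and 2) did as much. Genes are not independent replicates, so no p-value is given.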
